A study of Homo sapiens with 3 samples.

How the data were processed

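RNA was extracted from 3 biopsies of melanoma tissue with a mirVana kit and made into stranded poly(A) libraries with a KAPA mRNA kit, sequenced as paired ends, per the labels' protocols. The deposited table gives FPKM values, computed by the authors, for 25268 gene symbols and 1 column per biopsy. The submitters' processing notes name TopHat, TopHat2, Cuffnorm, Cuffdiff and the human build hg19. They give no roles or versions, and the annotation, the filters and the library normalization are not given in the sources used here. The table holds no counts, so the sequencing depth behind each value is unknown and no counting interval could be given. FPKM by its usual definition corrects for transcript length and for the number of mapped fragments. Under that definition a gene that takes a large part of a library lowers the others. Whether the libraries here were scaled otherwise is unknown. Values of 0 may be failed estimates, and folds against them are not given. The table has no coordinates and the reference annotation at hand is on GRCh38, so no positions are printed.

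Groups were taken from the treatment label: 1 baseline biopsy and 2 on-treatment biopsies taken on day 15. All 3 come from 1 patient, and the number of biopsies, not of patients, is the n. Before any calculation 132 symbols were left out: genes tied to sex, immunoglobulin and T cell receptor segments, and genes that only some people carry or express. Genes with a mean FPKM of at least 1 over the 3 libraries were tested, 13644 in all, and 5614 of the remaining symbols were at 0 in every library. Values were analysed as log2(FPKM + 1), with a pseudocount of 1. The test was limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a mean-variance trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 1 residual degree of freedom, from the difference between the on-treatment biopsies, and a prior of 2.52 degrees of freedom. Beside it, genes at least 2-fold from baseline in the same direction in both biopsies were counted. Chance values for that count came from 20 simulations of unchanged libraries that share a baseline, with spreads drawn from the fitted prior. Differences between the on-treatment biopsies were described by size alone.

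The design, the alternatives and 37 gene lists were fixed before the data were examined. They cover MAPK targets, melanocyte and melanoma markers, less differentiated states, cell cycle, immune, stromal, vessel, skin, fat, muscle and blood cells, interferon and antigen presentation, metabolism, growth factors, apoptosis, early response, ribosome, histones and reference genes. The 36 lists with at least 5 genes tested were compared with the other genes by camera in limma with an inter-gene correlation preset at 0.01 and, as an alternative, estimated per list. The estimate rests on 1 residual degree of freedom, so a list that does not pass with it is not shown to be unchanged. The preset takes the genes of a list as nearly independent, and genes are not replicates of the treatment. Small p-values with the preset therefore describe these libraries and do not measure a spread between biopsies. List medians were also ranked among 10000 random lists of equal size, matched on mean expression in 20 bins. Gene p-values were also adjusted over each list alone, with no adjustment across the lists. Genes that passed in this way are therefore not calls over all genes, where 0 passed. Some lists share members, and no list was chosen by the study on these samples. The genes named in the text followed a fixed rule: the 12 in each direction with the largest smaller difference of the 2 biopsies from baseline, the 8 in each direction with the largest difference between the biopsies, the 4 members of each list with the largest smaller difference, every MAPK target, and 7 genes chosen by name. Small RNAs with microRNA or snoRNA symbols and uncharacterised loci were tested but not named, and some genes that the rule names are not reported here.

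The scripts were tested on 10 simulated data sets of 13644 genes each, with genes changed by known amounts in the comparison of treatment with baseline. Mean estimated differences were 0.96, 2.01, 3.07 and 3.97 for simulated log2 changes of 1, 2, 3 and 4. Of 500 genes changed by 4 on the log2 scale, 97.8% had an unadjusted p under 0.05 and 0 passed the adjusted threshold. The gene test thus called no change of that size in these simulations. Each simulation changed only a small part of the genes, and the adjusted p depends on that part. The simulations therefore do not settle what the test could call in the real data. For unchanged genes 4.99% had an unadjusted p under 0.05. Of 40 lists changed by 1 on the log2 scale, 40 passed camera with the preset correlation and 0 with an estimated one, and 0 of 320 unchanged lists passed either. The simulations draw each gene's error independently, so they do not test the preset for lists whose genes vary together. The alternatives were pseudocounts of 0.1 and 5, filters of a mean FPKM above 0 and of at least 5, median-of-ratios, quantile and equal-sum (TPM) scaling, limma without the trend, 1.5-fold and 4-fold limits, and each on-treatment biopsy left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.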

Results

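Poly(A) RNA was sequenced from 3 tumour biopsies of 1 patient with melanoma. One biopsy was taken before treatment with inhibitors of the MAPK pathway, the growth-signalling cascade that runs through BRAF and MEK. The other 2 were taken on day 15 of combined BRAF and MEK inhibitor treatment and are called on-treatment biopsies 1 and 2. The question was how the transcriptome of the tumour tissue differed during treatment from that before it. Expression was given as FPKM, the number of sequenced fragments scaled to transcript length and library size, for 25268 gene symbols. The FPKM values summed to 443572 at baseline, 586390 in on-treatment biopsy 1 and 457723 in on-treatment biopsy 2. FTL, the ferritin light chain, took 5.50% of the sum in on-treatment biopsy 1, against 0.620% at baseline and 1.29% in on-treatment biopsy 2. Across the 13644 genes with a mean FPKM of at least 1, Pearson's r of log2(FPKM + 1) was 0.791 between baseline and on-treatment biopsy 1. It was 0.860 between baseline and on-treatment biopsy 2 and 0.864 between the on-treatment biopsies. Genes are not independent replicates, so these correlations only describe the libraries.

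WISP2, RBP4 and ELN were among the genes that stood most above baseline in both on-treatment biopsies, and VGF, SERPINA3 and MMP1 among those most below it. Differences are on the log2(FPKM + 1) scale, which understates changes of low genes, with the limma standard error. Among the 12 genes most consistently higher were WISP2, a secreted matricellular protein, with 0.609 FPKM at baseline and 142 and 62.6 on treatment (log2 difference 5.89 ± 0.62). RBP4, a retinol carrier, went from 0.189 to 42.9 and 54.3 FPKM (5.37 ± 0.35), and ELN, elastin, from 1.03 to 74.9 and 66.6 FPKM (5.14 ± 0.32). The fat-cell genes ADH1B, PLIN1, FABP4, GPD1, CIDEC and ADIPOQ were also in this group, as were MFAP4, HSPB6 and the chemokine CCL14. CIDEC and ADIPOQ were listed at 0 at baseline, and reached 22.4 and 23.7 FPKM, and 19.0 and 23.3 FPKM, on treatment. Among the 12 genes most consistently lower, VGF, a neuropeptide precursor, had 1322 FPKM at baseline and 3.79 and 4.91 on treatment (log2 difference -7.96 ± 0.34). SERPINA3, a protease inhibitor, went from 178 to 0.763 and 2.26 FPKM (-6.22 ± 0.52), and MMP1, an interstitial collagenase, from 894 to 56.0 and 1.06 FPKM (-6.37 ± 2.23). The other genes of this group were NELL1, PI15, BAALC, CBLN2, PIEZO2, the keratins KRT6A and KRT6C, and the small RNAs SNAR-G1 and SNAR-F. The SNAR, KRT6, tryptase, haemoglobin alpha, histone and LGALS7 genes have near-identical copies that share reads, so their values are uncertain.

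In total 982 genes were at least 2-fold higher and 740 at least 2-fold lower in both on-treatment biopsies than at baseline. Both comparisons use the same baseline library, and 20 simulations of unchanged libraries gave 334 and 360 genes on average. Independent lists of the same lengths would share 218 and 144 genes. The covariance of the log2 differences of the on-treatment biopsies was 0.684, against 0.378 in the simulations, and their correlation across genes was 0.626 against 0.5002. With 1 baseline library the control could not be split, so part of the excess may come from it. The direction was the same in both biopsies for 77.9% of genes, where chance gives 66.7%. No gene passed an adjusted p of 0.05 in limma with Benjamini-Hochberg adjustment (lowest 0.311), while 832 genes were higher and 844 lower at an unadjusted p under 0.05 (863 and 828 in limma without the trend, where 0 genes passed too). Scaling the libraries to the same sum gave 365 higher and 230 lower genes past the threshold, with infinite prior degrees of freedom. These gene p-values measure only the spread between 2 biopsies of 1 patient, with 1 residual degree of freedom. The lone baseline biopsy is assumed to vary like them.

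Most of the listed MAPK target transcripts were lower on treatment, 18 of 22 in both biopsies. Of 22 MAPK target genes tested, 10 were at least 2-fold lower in both biopsies and none was 2-fold higher in both. The list median was -1.40 in on-treatment biopsy 1 and -1.08 in on-treatment biopsy 2. DUSP4, a phosphatase that dampens ERK, went from 65.4 to 8.04 and 13.2 FPKM (log2 difference -2.55 ± 0.43). The feedback inhibitor SPRY4 went from 36.6 to 7.18 and 6.56 FPKM (-2.26 ± 0.32). The ETS-family transcription factor genes ETV4 (-2.80 ± 0.47), ETV5 (-1.73 ± 0.31) and ETV1 (-1.42 ± 0.45) were lower, and so were FOSL1 (-2.29 ± 0.32), LIF (-2.43 ± 0.36), SPRY2 (-1.72 ± 0.32), DUSP5 (-1.23 ± 0.36) and SPRED3 (-1.36 ± 0.41). SPRED1, SPRED2, PHLDA1, CCND1, EPHA2, MYC and SPRY1 were lower in both by less than 2-fold in at least 1 biopsy. DUSP6, a phosphatase specific for ERK, differed between the biopsies, with 64.1 FPKM at baseline and 44.4 and 15.4 on treatment. EGR1 was the 1 member higher in both, with 38.9, 49.1 and 71.3 FPKM in the baseline biopsy and on-treatment biopsies 1 and 2. The values of EGR3 were 7.83, 3.68 and 9.02 FPKM, those of EPHA4 1.37, 0.836 and 2.99, and those of KCNN4 4.90, 19.0 and 1.77. The list passed camera with a preset correlation (adjusted p = 6.19e-07), but not with an estimated one (adjusted p = 0.575 with an estimated correlation). No member passed over all genes, and 7 passed when adjusted over the list alone. Melanoma and melanocyte markers had a median of -1.07 in on-treatment biopsy 1 and -0.25 in on-treatment biopsy 2.

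Cell-cycle genes were lower in both on-treatment biopsies, more so in biopsy 2. All 33 mitosis genes tested were lower in both, 31 of them at least 2-fold, with medians of -1.82 in biopsy 1 and -3.09 in biopsy 2. CCNB1, cyclin B1, went from 36.1 to 4.87 and 1.89 FPKM (log2 difference -3.17 ± 0.57). UBE2C, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, went from 79.9 to 12.3 and 1.70 FPKM (-3.76 ± 1.11). MYBL2 (-3.63 ± 1.04) and the checkpoint kinase gene BUB1 (-2.95 ± 0.50) were lower to a like extent, and the proliferation marker MKI67 went from 16.7 to 3.88 and 0.558 FPKM (-2.68 ± 0.83). All 32 DNA replication genes tested were lower in both biopsies, 19 of them at least 2-fold, with medians of -1.06 and -1.69. TYMS, thymidylate synthase, went from 61.8 to 12.1 and 13.8 FPKM (-2.17 ± 0.32), and MCM4 (-2.05 ± 0.31), CDC6 (-2.48 ± 0.52) and CCNE2 (-2.35 ± 0.50) were lower too. Adjusted over the list alone, 28 mitosis genes and 0 replication genes passed, and 0 passed over all genes. The adjusted p in camera was 1.45e-14 for mitosis and 8.68e-12 for replication, and adjusted p = 0.575 with an estimated correlation for each. The replication-dependent histone genes, whose transcripts lack a poly(A) tail, had medians of -0.86 and -0.10 over 10 genes and did not pass camera (adjusted p = 0.119, and 0.00302 without the filter). HIST1H4C went from 4.37 to 0.608 and 0.494 FPKM.

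Pigmentation genes went both ways. Of 23 melanocyte-lineage genes tested, 2 were at least 2-fold lower in both biopsies, KIT (log2 difference -1.79 ± 0.42) and BACE2 (-1.59 ± 0.33). The list medians were -0.47 in biopsy 1 and 0.27 in biopsy 2, and the list did not pass camera (adjusted p = 0.478). MITF, the master transcription factor of melanocytes, had 54.6 FPKM at baseline and 39.1 and 66.1 on treatment. DCT, a melanin synthesis enzyme, had 177, 282 and 488 FPKM, and GPM6B had 235, 70.1 and 131. Of 14 other melanoma markers, 6 were at least 2-fold lower in both biopsies and the medians were -1.29 and -0.71. SERPINE2, a protease inhibitor, went from 1124 to 77.2 and 180 FPKM (-3.24 ± 0.64), and MIA, a secreted melanoma protein, from 429 to 153 and 167 FPKM (-1.42 ± 0.32). The log2 differences of MAGEA12 and CDH19 were -1.79 ± 0.48 and -1.70 ± 0.47. Camera gave an adjusted p of 0.00101 for the melanoma markers, and adjusted p = 0.646 with an estimated correlation. Adjusted over the list alone, 0 members passed in either list.

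Lists for less differentiated melanoma states were mixed. The 16 neural crest stem-like genes had medians of 0.67 and 0.89, with 5 at least 2-fold higher and 1 at least 2-fold lower in both biopsies. AQP1, a water channel also found in vessel walls, went from 25.2 to 187 and 205 FPKM (log2 difference 2.91 ± 0.31), and TMEM176B, ANXA1 and A2M were higher by 2.47 ± 0.46, 2.39 ± 0.56 and 1.36 ± 0.32. These genes are also expressed by myeloid, endothelial or stromal cells, and the combined medians of the macrophage, endothelial and fibroblast lists were 2.42, 1.84 and 2.56. The neural crest genes NGFR and NES, chosen after their values were seen, had log2 differences of -0.15 ± 0.74 and -1.13 ± 0.32. The neural crest list passed camera (adjusted p = 0.00221, and adjusted p = 0.575 with an estimated correlation). Adjusted over the list alone, 1 member passed. The 23 dedifferentiation genes had medians of 0.29 and 0.34 and did not pass (adjusted p = 0.151). Their combined median was 0.13, and it turned negative, -0.12, when only genes with a mean FPKM of at least 5 were kept. Among them the receptor tyrosine kinase gene AXL (2.10 ± 0.34), CTGF (2.88 ± 0.32) and PDGFRB (2.38 ± 0.30) were higher, while FOSL1 was lower. Adjusted over the list alone, 6 members passed, 3 of them higher. The 20 TGF-beta and mesenchymal transition genes also went both ways, with medians of 0.43 and 0.04 (adjusted p = 0.0934, and 0.0233 with a mean FPKM of at least 5). N-cadherin, CDH2, went from 8.20 to 0.858 and 0.593 FPKM (-2.42 ± 0.39) and the receptor gene TGFBR2 was higher, at 68.4 and 77.7 FPKM on treatment (2.30 ± 0.32). The values of TGFB3 were 7.27, 24.2 and 24.7 FPKM, and those of ITGB3 61.7, 23.6 and 6.01.

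Genes of connective tissue, vessels and fat were higher in both on-treatment biopsies. Of 29 fibroblast and collagen matrix genes, 24 were at least 2-fold higher in both and none was 2-fold lower, with medians of 3.15 in biopsy 1 and 2.00 in biopsy 2. COL1A1, the main collagen of skin, went from 142 to 5205 and 1502 FPKM (log2 difference 4.29 ± 0.90), DCN, decorin, from 28.9 to 427 and 404 FPKM (3.80 ± 0.31), and CXCL12 from 6.87 to 118 and 138 FPKM (4.03 ± 0.32). Complement C3 was higher by 3.79 ± 0.35. Of 20 endothelial genes, 15 were at least 2-fold higher in both, with medians of 1.79 and 1.85. The tight-junction gene CLDN5 went from 3.21 to 52.9 and 44.1 FPKM, and VWF, CD34 and PECAM1 were higher by 2.61 ± 0.32, 2.56 ± 0.30 and 2.56 ± 0.35. Of 15 pericyte and smooth muscle genes, 11 were at least 2-fold higher in both (medians 1.59 and 2.12), among them ACTG2, TAGLN, CNN1 and LMOD1. TAGLN, transgelin, went from 22.6 to 342 and 242 FPKM. Lymphatic endothelial genes had 4 of 7 members at least 2-fold higher in both (medians 1.64 and 1.93), MMRN1, TFF3, PDPN and LYVE1. Of 15 adipocyte genes, 14 were at least 2-fold higher in both, with medians of 3.52 and 3.35, or 11.5-fold and 10.2-fold. PLIN1, the coat protein of lipid droplets, went from 0.0303 to 24.7 and 40.5 FPKM, GPD1 from 0.0903 to 25.9 and 24.1, and FABP4 from 5.93 to 862 and 162. Skeletal muscle genes were low, with medians of 2.16 and 0.94 over 7 genes, and TNNT3 was the 1 member at least 2-fold higher in both. MYLPF had 0.119, 9.88 and 1.19 FPKM and TNNI2 0.619, 5.94 and 1.99, and TNNC2 was listed at 0 at baseline. The adjusted p in camera was 3.09e-17 for fibroblasts, 1.88e-14 for endothelium, 1.57e-10 for pericytes, 1.93e-04 for lymphatic endothelium, 2.11e-13 for adipocytes and 0.00163 for muscle. For each of these, adjusted p = 0.575 with an estimated correlation. Adjusted over the lists alone, 20 fibroblast, 16 endothelial, 9 pericyte, 4 lymphatic, 14 adipocyte and 0 muscle genes passed, all of them higher.

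Macrophage, MHC class II, T cell and cytotoxic lymphocyte genes were higher in both on-treatment biopsies. Of 26 macrophage genes, 21 were at least 2-fold higher in both biopsies, with medians of 3.25 in biopsy 1 and 1.35 in biopsy 2, or 9.49-fold and 2.55-fold. CD14, a co-receptor for lipopolysaccharide, went from 28.1 to 363 and 121 FPKM (log2 difference 2.86 ± 0.79), the scavenger receptor gene MARCO from 0.292 to 22.6 and 5.58 FPKM (3.27 ± 0.91), MS4A6A from 8.29 to 66.3 and 44.6 FPKM and SIGLEC1 from 1.83 to 23.7 and 11.4 FPKM. Of 9 genes of MHC class II presentation, 8 were at least 2-fold higher in both (medians 3.40 and 1.80), with CD74, the invariant chain, at 175, 2331 and 1057 FPKM. HLA-DRA, HLA-DMA and HLA-DPA1 were higher by 2.93 ± 0.63, 2.76 ± 0.67 and 2.36 ± 0.42. Of 13 T cell genes, 6 were at least 2-fold higher in both (medians 2.08 and 0.96), with CD3D at 0.316, 9.08 and 2.75 FPKM, CD3E at 0.745, 11.4 and 3.82, and CD2 at 0.446, 10.6 and 2.87. CD4, which macrophages express too, had 6.94, 138 and 24.5 FPKM. CD8A went from 0.331 to 2.11 and 1.72 FPKM (1.13 ± 0.41). Of 10 cytotoxic lymphocyte genes, 6 were at least 2-fold higher in both (medians 1.58 and 1.19), among them NKG7 (2.52 ± 0.70), GZMA (2.41 ± 0.64) and GZMB (1.47 ± 0.45). GZMK was listed at 0 at baseline, with 4.42 and 1.93 FPKM on treatment. Camera gave an adjusted p of 3.66e-10 for macrophages, 5.40e-07 for MHC class II, 9.43e-06 for T cells and 6.23e-05 for cytotoxic cells, and adjusted p = 0.575 with an estimated correlation for each. Adjusted over the lists alone, 7 MHC class II genes passed and 0 of the other 3 lists.

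Immune checkpoint genes were higher as a list, with unlike values for the ligands of PD-1. PDCD1LG2, which encodes PD-L2, had 0.347 FPKM at baseline and 4.91 and 1.90 on treatment (log2 difference 1.62 ± 0.61), while CD274, which encodes PD-L1, had 2.51, 2.66 and 1.95 FPKM (-0.09 ± 0.40, with a sign that changed with the scaling). The difference between the 2 genes was not tested. Of 12 checkpoint genes, 5 were at least 2-fold higher in both biopsies (medians 1.60 and 1.06), LGALS9 (3.07 ± 0.94), C10orf54, which encodes VISTA (2.32 FPKM at baseline, 24.4 and 12.9 on treatment), CD86 (2.17 ± 1.00), HAVCR2 and PDCD1LG2. Macrophages also express these 5 genes, and the macrophage medians were 3.25 and 1.35. The T cell checkpoint genes PDCD1, CTLA4 and TIGIT, chosen after their values were seen, had a mean FPKM under 1 and were not tested. Their low values were higher in both on-treatment biopsies. PDCD1 had 0.0901 FPKM at baseline and 1.08 and 0.370 on treatment, CTLA4 0.168, 0.649 and 0.490, and TIGIT 0.0630, 1.18 and 0.893. Of 21 interferon-gamma response genes, 9 were at least 2-fold higher in both (medians 0.91 and 1.29), with APOL3 at 1.73, 19.0 and 17.2 FPKM, GBP1 at 4.59, 20.9 and 19.9, GBP4 at 1.29, 6.16 and 11.1, and CXCL9 at 1.30, 6.09 and 8.07. Chemokine genes had 5 of 22 at least 2-fold higher in both (medians 1.17 and 0.84), with CCL18 at 10.4, 328 and 44.8 FPKM and CCL5 at 4.06, 37.2 and 11.4. Of 23 type I interferon response genes, 3 were at least 2-fold higher in both, EPSTI1, MX2 and XAF1 (medians 0.14 and 0.83), and OAS1 was higher by 0.78 ± 0.31. MHC class I genes had 3 of 16 at least 2-fold higher in both (medians 0.68 and 0.37), HLA-B, HLA-E and HLA-F, which share reads with their relatives, and B2M was higher by 1.42 ± 0.55. Of 10 dendritic and mast cell genes, 4 were at least 2-fold higher in both (medians 0.88 and 1.34), the mast cell genes TPSAB1, TPSB2 and CPA3 and the dendritic cell gene CLEC10A. Lymph node stroma genes had 3 of 5 at least 2-fold higher in both, among them CLU and LTF, with CCL21 at 9.95, 12.4 and 15.7 FPKM (medians 1.12 and 1.21). CLU and LTF are also made by many other cells. The adjusted p in camera was 3.29e-04 for checkpoints, 1.57e-04 for interferon-gamma, 2.67e-04 for chemokines, 0.00136 for dendritic and mast cells and 0.00192 for lymph node stroma, and for these 5 lists adjusted p = 0.575 with an estimated correlation. It was 0.00257 for type I interferon (adjusted p = 0.705 with an estimated correlation) and 0.015 for MHC class I (adjusted p = 0.633 with an estimated correlation). The MHC class I call was lost, at 0.0554, when libraries were scaled to the same sum. Adjusted over the lists alone, 3 dendritic and mast cell genes passed and 1 each of the interferon-gamma, chemokine and lymph node lists. The 6 B and plasma cell genes tested (medians 0.41 and 0.27) and the 8 neutrophil genes (medians 2.37 and -0.23) did not pass, with adjusted p of 0.317 and 0.25. The neutrophil list did pass without the filter (0.0427) and when scaled to the same sum (0.0426), and S100A8, lower, passed when adjusted over the list alone. Under scaling to the same sum the prior degrees of freedom were infinite, so the opposite directions of the biopsies did not enter. In these lists IGJ was higher by 1.97 ± 0.46, the values of CD79B were 0.591, 1.82 and 1.78 FPKM, of FCRLA 2.23, 0.947 and 1.83, and of CD22 1.89, 5.09 and 1.93. S100A8, also made by keratinocytes, went from 166 to 32.9 and 26.6 FPKM, FPR1 from 2.91 to 7.71 and 8.29, CSF3R had 0.563, 14.3 and 3.11, and FCGR3B 1.03, 6.85 and 2.23.

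Receptor tyrosine kinase and ligand genes were higher as a list, and several of its members are also stromal genes. Of 21 receptor tyrosine kinase and ligand genes, 10 were at least 2-fold higher and 1, KIT, at least 2-fold lower in both biopsies, with medians of 0.13 and 1.45. IGF1 went from 0.436 to 8.91 and 11.4 FPKM (log2 difference 2.95 ± 0.37) and PDGFRA was higher by 2.00 ± 0.32, beside PDGFRB and AXL. The list passed camera (adjusted p = 5.15e-04, and adjusted p = 0.575 with an estimated correlation), and 8 members passed when adjusted over the list alone, 7 of them higher. Immediate-early genes had 5 of 23 at least 2-fold higher in both (medians 0.33 and 0.71), with JUN at 23.2, 67.7 and 55.4 FPKM, ZFP36 at 25.4, 63.6 and 70.3, KLF2 at 16.3, 39.8 and 63.2 and EGR2 at 2.62, 15.3 and 7.75. They passed camera (adjusted p = 0.00318, and adjusted p = 0.575 with an estimated correlation). Of 16 apoptosis regulators, 1 was at least 2-fold higher and 1 at least 2-fold lower in both biopsies, and the list did not pass camera (adjusted p = 0.966). These were BMF, at 1.55, 18.7 and 8.83 FPKM, and PMAIP1, which encodes NOXA, at 23.2, 1.42 and 3.61 FPKM, both pro-apoptotic. The pro-apoptotic gene BAK1 had 30.5, 24.4 and 18.6 FPKM and the anti-apoptotic gene BCL2L1 35.1, 53.4 and 57.7 FPKM. Glycolysis and hypoxia genes had medians of -0.05 and -1.31 over 24 genes (adjusted p = 0.22 in camera). The adjusted p was 0.0195 when scaled to the same sum, where infinite prior degrees of freedom left out each gene's own spread. Among them VEGFA had 48.4, 18.0 and 10.5 FPKM, EGLN3 5.92, 43.2 and 27.4, ADM 16.0, 45.8 and 31.5 and BNIP3 52.6, 31.2 and 20.6. Respiration genes had medians of -0.06 and -0.31 over 26 genes (adjusted p = 0.222), with CYCS, cytochrome c, at 63.3, 22.8 and 26.0 FPKM, PPARGC1A at 3.08, 1.16 and 0.967, NDUFS1 at 40.3, 16.9 and 22.2 and ATP5A1 at 348, 220 and 221. The 25 reference genes had medians of -0.10 and -0.19 (adjusted p = 0.394), and TFRC, the transferrin receptor, was the 1 at least 2-fold lower in both, at 158, 24.5 and 8.35 FPKM. The 40 ribosomal protein genes passed camera (adjusted p = 0.0278, and adjusted p = 0.575 with an estimated correlation) with a median of 0.17, which was -0.17 after quantile normalization and -0.05 after scaling to the same sum. The call was also lost without the filter (adjusted p = 0.108). None of them differed 2-fold in both, with RPS14 at 796, 1456 and 1386 FPKM. The median of all tested genes was -0.19 in biopsy 1 and -0.04 in biopsy 2, and camera compares each list with the other genes. The combined median of all genes, -0.12, became -0.34 after scaling to the same sum and 0.01 after median-of-ratios scaling.

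**Figure D1:**
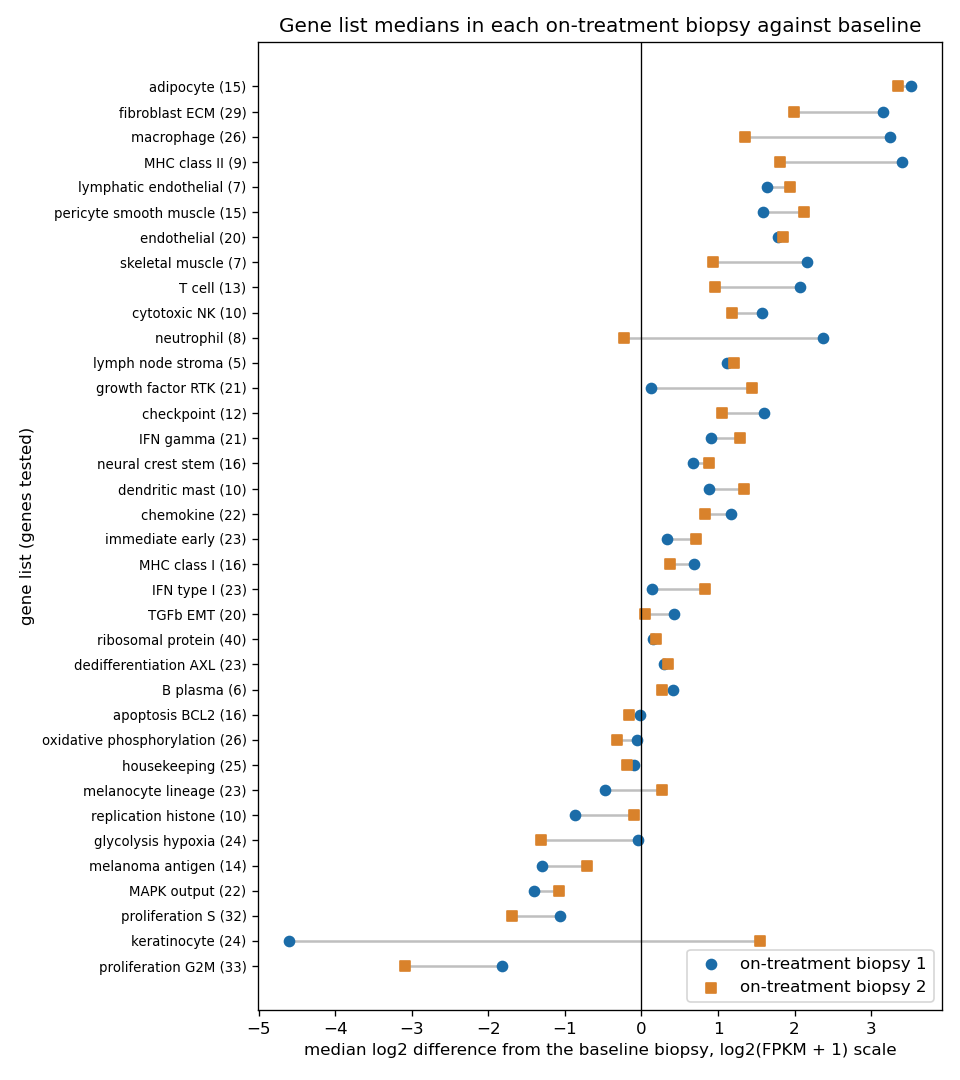
Median log2 difference from the baseline biopsy, on the log2(FPKM + 1) scale, for the 36 gene lists with at least 5 genes tested, with the number of genes in brackets; circles are on-treatment biopsy 1, squares on-treatment biopsy 2, and the grey line joins them. The adipocyte list lies highest (3.52 and 3.35), the mitosis list (proliferation G2M) at -1.82 and -3.09, and the keratinocyte list at -4.60 and 1.55.

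Keratinocyte transcripts were lower, and macrophage transcripts higher, in on-treatment biopsy 1 than in on-treatment biopsy 2. The comparison has 1 library on each side, so it has no replicate check and no p-value. On-treatment biopsy 1 had 925 genes at least 2-fold above biopsy 2, and 935 genes lay at least 2-fold the other way. The share of these genes higher in biopsy 1, 49.7%, was 26.5% when the libraries were scaled to the same sum. All 24 keratinocyte genes were at least 2-fold lower in biopsy 1, with a median difference of -5.77. KRT1, a keratin of the upper epidermis, had 0.638 FPKM in biopsy 1, 2905 in biopsy 2 and 752 at baseline. KRT10 had 10.5, 3673 and 1127 FPKM, and LOR, loricrin, 0.229, 569 and 139, in the same order. KRT2, LGALS7B and SBSN showed the same pattern, and KRTDAP and SPRR1B were listed at 0 in biopsy 1. The keratins of activated epidermis, KRT6A and KRT16, were instead highest at baseline, with 225 and 81.5 FPKM against 18.3 and 7.90 in biopsy 2. KRT17 and DSG3 had 41.6 and 10.7 FPKM at baseline, 3.13 and 0.652 in biopsy 1 and 24.2 and 8.54 in biopsy 2. Over both on-treatment biopsies the keratinocyte list did not pass camera (adjusted p = 0.0753), and it did pass with a pseudocount of 0.1 (0.0493), median-of-ratios scaling (0.0252) and scaling to the same sum (1.68e-24, with infinite prior degrees of freedom, so that the opposite directions of the biopsies did not enter). With the preset replaced, adjusted p = 0.805 with an estimated correlation.

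Macrophage genes were higher in biopsy 1 as a list, and MMP9, MMP12 and SPP1 were among the genes with the largest difference between the biopsies. MMP9, a gelatinase, had 4914 FPKM in biopsy 1, 4.14 in biopsy 2 and 26.9 at baseline. The elastase gene MMP12 had 826, 0.233 and 0.276 FPKM, SPP1, osteopontin, 7531, 19.7 and 147, and CHI3L1, a chitinase-like protein, 335, 4.79 and 2.52. ADAM8, HK3 and VMO1 were higher in biopsy 1 by 5.81, 4.99 and 5.07 on the log2 scale. The macrophage median was 1.80 higher in biopsy 1, the neutrophil median 1.82, the fibroblast median 1.01, the T cell median 1.26 and the mitosis median 1.15. Each of these lay in the top 2.5% of 10000 random lists of equal size matched on mean expression. The random lists were drawn without regard to which genes vary together. A list of genes that do can thus reach a tail with a small shift, so these ranks only describe the 2 libraries. The ribosomal protein list, for instance, lay at percentile 2.27 with a median difference of 0.05. Of the 36 lists, 13 lay in the top 2.5% and 7 in the bottom 2.5%. The keratinocyte, melanocyte-lineage (-1.01), melanoma marker (-0.86) and type I interferon (-0.68) lists were among those 7. The red cell genes HBB, HBA1 and HBA2 were highest in biopsy 2, with HBB at 794 FPKM against 25.6 in biopsy 1 and 19.1 at baseline. In the same order HBA1 had 84.1, 3.74 and 2.42 FPKM and HBA2 60.6, 2.66 and 1.04, and this list had only 3 genes tested and no list test.

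**Figure D2:**
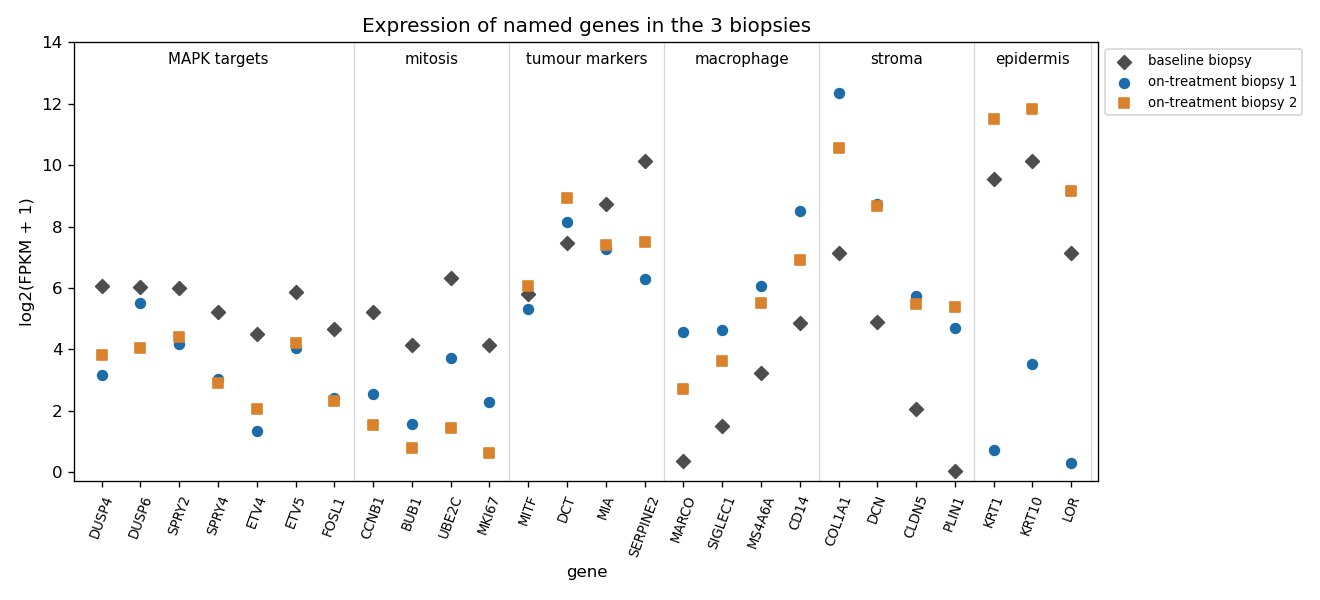
Expression as log2(FPKM + 1) of named genes in the baseline biopsy (diamonds) and on-treatment biopsies 1 (circles) and 2 (squares), 1 library per symbol. The tumour markers shown are MITF, DCT, MIA and SERPINE2. MAPK target and mitosis genes lie below baseline in both on-treatment biopsies (SPRY4 at 36.6, 7.18 and 6.56 FPKM), macrophage and stromal genes above it (CD14 at 28.1, 363 and 121 FPKM), and KRT1, KRT10 and LOR lie low in biopsy 1 alone.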

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

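The counts of 2-fold genes depended on the pseudocount and the limit, and the list calls on whether camera used the preset or an estimated correlation. With a pseudocount of 5 the genes 2-fold from baseline in both biopsies were 401 higher and 325 lower, and those between the biopsies 551 and 443. With a mean FPKM of at least 5, 487 were lower in both, 498 higher in biopsy 2, and 8 lists stood out in biopsy 1, where 28 lists kept 5 genes. At 1.5-fold there were 1841 higher and 1961 lower in both and 1774 and 2105 between the biopsies, and at 4-fold 244, 124, 228 and 361. With biopsy 1 or biopsy 2 left out, 1625 to 1828 genes were 2-fold higher and 1027 to 1914 lower in the other, since only 1 biopsy must then pass. Scaling to the same sum gave 1907 genes higher in biopsy 2 and, in limma, 365 higher and 230 lower genes past an adjusted p of 0.05. There the prior degrees of freedom became infinite, so each gene's own spread was ignored. In the other settings 0 genes passed (lowest adjusted p 0.232 to 0.446). The balance of genes 2-fold from baseline in both biopsies turned with the scaling. It was 1038 higher and 1091 lower after scaling to the same sum, and 1126 higher and 578 lower after median-of-ratios scaling. Median-of-ratios scaling kept 982 of the 982 higher and 578 of the 740 lower genes. With an estimated correlation 0 lists passed up and 0 down, and in the self-test it called 0 of 40 lists changed by 1 on the log2 scale, the only size simulated. For the adipocyte list the estimate, -0.0286, lay below the preset of 0.01, yet the unadjusted camera p went from 2.34e-14 to 0.0777. A larger correlation thus does not account for the loss in that list, and the estimated variant cannot show that a list is unchanged. The ribosomal protein median was -0.1734 after quantile normalization and -0.0527 after scaling to the same sum, and the cause was not tested. Of 198 named genes, 196 kept their sign under each scaling, filter and pseudocount, and MITF and CD274 did not. No paired analysis was possible because there was only 1 baseline biopsy, from 1 patient. Depth is unknown, and the single baseline biopsy limits each comparison with it.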

Other observations

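The tests of tumour share, macrophage share, the C1Q genes and the splits, and the limits set for each test in this part, were chosen after the results were seen, while the gene lists and the scalings were planned. The genes in this paragraph were chosen after their values were seen and are given as values only. MMP13, a collagenase, had 34.2 FPKM at baseline and 3.02 and 0.602 on treatment, and the chromatin gene HMGA2 16.8, 0.321 and 0.954. STC1, a secreted glycoprotein, had 24.4, 1.52 and 1.73 FPKM. FTL, the ferritin light chain, had 2750 FPKM at baseline, 32251 in biopsy 1 and 5921 in biopsy 2, FTH1 1770, 7165 and 2177, APOE 1763, 9393 and 3276, and CTSD, cathepsin D, 590, 4527 and 843. CHIT1, a chitinase of lipid-laden macrophages, was listed at 0 at baseline, with 23.3 and 1.07 FPKM on treatment. In biopsy 2 the sweat and apocrine gland genes DCD, MUCL1 and SCGB2A2 had 42.4, 20.1 and 26.3 FPKM, and they were listed at 0 at baseline. PMEL, a melanosome protein, had 645 FPKM in biopsy 2 against 39.8 at baseline and 37.8 in biopsy 1. KRT14 had 693 FPKM at baseline and 1154 FPKM in biopsy 2.

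The first pattern is that mitosis genes and MAPK targets were lower in both on-treatment biopsies. A smaller share of tumour cells would lower tumour markers by about as much, but the mitosis median minus that of 37 tumour markers was -0.744 (95% bootstrap interval over genes -1.33 to -0.44) in biopsy 1 and -2.84 (-3.58 to -2.45) in biopsy 2. This argues against a smaller share as the whole cause, more weakly in biopsy 1. There the melanoma markers outside pigmentation had a median of -1.29, against -1.82 for mitosis, and no interval was computed for that gap. In biopsy 2 the same medians were -0.71 and -3.09. The mitosis median of -2.32 under the least favourable scaling argues against the scaling. For the MAPK targets the difference was -0.33 (-0.98 to 0.12) in biopsy 1 and -0.83 (-1.79 to -0.39) in biopsy 2. The biopsy 2 value leans on the pigment genes among the markers, whose list median was 0.27 there. The 14 other melanoma markers had medians of -1.29 and -0.71, beside -1.40 and -1.08 for the MAPK targets, and this gap was given no interval. Taking both biopsies, a smaller tumour share cannot be told apart from lower MAPK output. Pigment genes may themselves be raised per cell during treatment, and a lower MAPK output under the inhibitors stays open as an untested hypothesis.

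The second pattern is that stromal lists were higher in both on-treatment biopsies. A smaller tumour share would raise the markers of each other cell type alike. The keratinocyte median was -4.60 (95% bootstrap interval over genes -5.76 to -3.76) in biopsy 1, but 1.55 (1.17 to 1.70) in biopsy 2. The adipocyte median lay above the endothelial one by 1.73 (0.12 to 2.86) and 1.496 (0.14 to 2.94). The adipocyte values in both biopsies and the keratinocyte value in biopsy 1 argue against a smaller share as the only difference from baseline. The intervals resample genes, not biopsies. They do not show how much of the stromal rise a smaller share made, so it stays open as a part of the cause. The lowest of the adipocyte, fibroblast and endothelial medians under the 3 scalings, 1.77, argues against the scaling. What part of the tissue each biopsy sampled, and a change of the stroma during treatment, stay open, since 1 baseline biopsy does not separate them.

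The third pattern is that macrophage genes were higher in biopsy 1 than in biopsy 2. By the usual definition of FPKM, the few genes with very high FPKM in biopsy 1 would lower the rest there, not raise them. The scalings were therefore no test of those genes as a cause. The macrophage median difference was 1.71 under the lower of the median-of-ratios and quantile scalings. A larger share of macrophages was set to show as 80% of the list at least 2-fold higher, and 61.5% was found (16 of 26 genes), so it stays open. Among members chosen after their values were seen, the list was uneven, with log2 differences between the biopsies of -0.28 for FOLR2, 0.34 for CD300LF and 0.42 for MRC1, against 3.77 for LILRB4 and 3.35 for LYZ. The largest ratio of biopsy 1 to biopsy 2 among C1QA, C1QB and C1QC was 1.41, with C1QB at 8.36 and 9.38 FPKM (10.4 at baseline) and C1QA (1.56 and 1.42) and C1QC (1.51 and 1.07) near the floor, but these genes were picked for their like levels and their counting was not checked against reads, so this value decides nothing.

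With each library in turn set against the others, 1722 genes lay at least 2-fold from both others in the baseline biopsy, 1195 in on-treatment biopsy 1 and 598 in on-treatment biopsy 2. The real split was thus the only 1 of the 3 splits with as many genes, and 3 splits are too few for a share under 0.05.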
